A study of Mus musculus with 54 samples.

How the data were processed

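Mouse bone marrow RNA was measured by bulk RNA sequencing in 46 libraries and by droplet single-cell RNA sequencing in 8 libraries. Per the labels' protocols, marrow was flushed from femurs and tibias, filtered, and treated with ACK buffer to lyse red blood cells. Bulk libraries were made from poly(A)-enriched, fragmented mRNA, and single-cell libraries with a 10x Genomics 3′ v3.1 kit. The labels name 3 wild type cell preparations and 7 leukemia models in whole marrow. They also name 8 groups of Kit-positive hematopoietic stem and progenitor cells (HSPC), 2 of them called EV and EV2 and taken here as empty vector controls. What the letters in the construct names stand for is not given in the sources used here, and the groups are called by their labels. The labels do not state that replicates came from separate animals, so every p-value measures only the spread between these samples.

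The authors' deposited bulk values are raw HTSeq gene counts, 1 table per library with 55536 gene rows, followed by HTSeq's own summary lines. Per the submitters' processing notes, reads were aligned to mm10 with HISAT2 version 2.1.0 and counted with HTSeq; the HTSeq version and its strand setting are not given in the sources used here. The deposited single-cell values are Cell Ranger UMI counts for called cells, and per the file headers they were made with Cell Ranger 7.1.0. The notes also name Seurat, without a version or settings. All 55536 bulk gene identifiers were found in GENCODE vM21, the annotation of GRCm38 (mm10) used here for symbols and positions, and positions are whole gene spans counted from 1. The 37 mitochondrially encoded genes were listed at 0 in every bulk library, so the list of mitochondrially encoded genes could not be tested there. Myl12b, Itgam and Igkc overlap other annotated genes, and their bulk counts near 0 are uncertain. Transgenes cannot be told from mouse transcripts in gene counts. Members of gene families with like sequences (T cell receptor constant genes, Oas1, Ifi200, Stfa, hemoglobin and mast cell protease genes) share reads that a counting tool may drop or assign to either copy.

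Marrow libraries held 4017079 to 15620208 gene counts. HSPC libraries held 8334829 to 19682988, except EV2 replicate 2, with 1187468. Between replicates of a group the mean chi-square per gene was 2.54 to 5.78, above what counting error alone gives. HTSeq's summary lines took 16.4 to 36% of all entries. The share of reads without a feature was 1.24 to 1.43% in the EV, CS, ΔRBD-S and ΔACD-S HSPC libraries. In the EV2, ROCK1-KD, MYLK and INF2-CA HSPC libraries it was 10.6 to 13.2%, and in the marrow libraries 6.98 to 18.4%. The HSPC libraries therefore fall into 2 technical sets, each with its own empty vector. A construct was called changed only where it passed against both EV and EV2 in 1 direction, and the values against each vector alone are printed beside the counts.

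Bulk counts were fitted with edgeR 4.0.16 in R 4.3.3, separately for the 30 marrow and the 16 HSPC libraries. The fit used TMM scaling, the filterByExpr low count filter by group, 1 coefficient per group, and glmQLFit with glmQLFTest, the edgeR quasi-likelihood test. This left 15995 marrow genes and 14635 HSPC genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. For the HSPC constructs the p of a gene was the larger of those against EV and against EV2, set to 1 where the signs differed, and the fold change was the smaller of both. Levels are CPM, counts scaled to library size, as the mean and SD of the libraries of a group, and single-gene errors on the log2 scale are standard errors of the fit. A fold against a group with no counts is a lower bound computed from a floor of 3 counts over that group's summed libraries. With 1 to 3 counts the ratio is given with an exact Poisson 95% interval. Intervals and floors cover counting error only, since bulk reads carry no molecular identifiers.

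Gene lists, comparisons, tests, marker genes and alternatives were fixed before the data were examined. The lists cover interferon-stimulated and interferon-gamma-inducible genes, cGAS-STING and nucleic acid sensing, NF-kB and cytokine genes, the actomyosin cytoskeleton, SRF/MRTF and YAP/TAZ targets, and oxidative phosphorylation. Others hold mitochondrial dynamics, vesicle release and ESCRT, glycolysis, cell cycle, ribosome biogenesis and MYC, ribosomal protein, p53, stress response, integrin and immediate early genes. The rest are markers of stem cells, the Hoxa-Meis1 leukemia programme, granule, neutrophil, monocyte, dendritic, MHC class I, B, T and NK, erythroid, megakaryocyte, mast, and stromal cells. Each list was tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison, and again with the correlation estimated from the data. A member that rose or fell passed the edgeR quasi-likelihood test over all genes tested, and counts adjusted over the list alone are given where they differ.

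Genes are named by a fixed rule. They passed the test, had at least 10 CPM in the higher group, and had every library of 1 group on one side of every library of the other. Of these, the 10 genes with the greatest fold change in each direction were taken for pooled comparisons, and 5 for single ones. For a pooled comparison a gene also had to pass in every single model. Predicted genes, pseudogenes, receptor segments and sex-linked genes were left out, and up to 4 called members of each list described were added. Rock1, Mylk, Inf2, Myl12b, Rhoa, Tmem173 and Cgas are reported whatever their values.

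Single cells were kept with at least 500 genes, 1000 UMIs and at most 10% mitochondrial UMIs, with scanpy 1.11.5 in Python 3.11.15. Doublets were called by Scrublet, run per library at an expected rate of 0.8% per 1000 cells. It called 14.5% of ΔRBD-S cells but only 4 of 9970 ΔRBD-L cells and 0 of 9877 MYLK cells, so doublets remain in the last pair, and clusters 12 and 14 held cells with high UMI totals. Clusters came from 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 with igraph 0.11.9. A cluster was named from the fixed markers where at least 3 of them were 2-fold above the summed wild type library, and left unnamed where its leading genes held more markers of another type or where UMIs were few and no marker led. There is 1 single-cell library per group, so no test was made: values are summed UMIs on the CPM scale with exact Poisson 95% intervals, and shares of cells with Clopper-Pearson 95% intervals. Free RNA in droplets adds UMIs of abundant transcripts to cells that do not express them. List medians in single cells were ranked against 10000 random lists of genes of like level.

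The alternatives were RLE scaling, no low count filter, DESeq2 1.42.0, a term for replicate number, a fit on the compared groups only, each empty vector alone, leaving out each library, and list tests with an estimated correlation. For single cells they were a looser filter of 200 genes, 500 UMIs and 20% mitochondrial UMIs, doublets kept, resolution 0.5, and cells thinned to 3000 UMIs. Chosen after seeing the data were other wild type references and pools without the INF2-CA leukemia libraries. The procedure was tested on simulated data made from these libraries. Few genes were changed in each simulation (67 at 2-fold), raised and lowered alike, far fewer than were called in the leukemia comparisons. At 2-fold, 94% of changed genes were recovered for the pooled leukemia comparison, 83.6% for CS leukemia, 85.1% for the pooled HSPC comparison and 70.1% for CS-HSPC. False calls were 4.26%, 6.63%, 0% and 0% of all calls in that order. Among models they were 10.7%, above the nominal rate. The simulated EV2 libraries were given the EV profile, so the 0% for HSPC does not carry over to the real vectors, which differed in 4264 genes. In the simulated CS leukemia comparison the list test called the 1 raised list and 0 of the other lists.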

Results

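Bulk RNA sequencing covered 30 marrow libraries in 10 groups of 3 and 16 HSPC libraries in 8 groups of 2, and single-cell RNA sequencing covered 8 marrow libraries, 1 per group. The wild type groups are labelled BM MNC (marrow mononuclear cells), HSPC (Kit-positive progenitors) and MP (lineage-negative, Kit-positive, Sca-negative myeloid progenitors). The leukemia models, labelled acute myeloid leukemia, are CS, ΔRBD-S, ΔRBD-L, ROCK1-KD, MYLK, INF2-CA and MYL12B-2E. ROCK1 is a kinase that raises myosin light chain phosphorylation, MYLK phosphorylates the same chain, MYL12B is that chain, and INF2 is an actin-polymerizing formin. The series title ties cytoskeletal change to leukemia and to STING, the adaptor of cytosolic DNA sensing encoded by Tmem173. The comparisons ask how each model's marrow differs from wild type marrow and from the other models, and what the constructs change in HSPC before leukemia. Library sizes are given above. The single-cell libraries gave 7481 to 11611 cells, at a median of 8367 to 18541 UMIs per cell.

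The wild type labels and the marker genes were set side by side first, since every leukemia value is read against them. Kit, the stem cell factor receptor, stood at 401 ± 16.6 CPM (SD, n = 3) in the libraries labelled WT BM MNC, 116 ± 11 CPM in those labelled WT HSPC and 571 ± 15.6 CPM in WT MP. Cd34, a progenitor surface marker, was at 219, 50.8 and 499 CPM in the same order. Genes of mature cells ran the other way: Mmp8, a neutrophil collagenase, was at 77.8 CPM in WT BM MNC and 1210 CPM in WT HSPC. The gap was smaller for the granule genes Ngp (9510 and 18400 CPM), Ltf (3940 and 9390 CPM) and Camp (2630 and 3880 CPM), which were at 7.01, 2.39 and 2.05 CPM in WT MP. Ighm, the immunoglobulin heavy chain of B cells, was at 813 and 8690 CPM, and Hbb-bs, an adult beta globin, at 52.9 and 2470 CPM. The Y-linked Ddx3y was at 90.4 CPM in WT BM MNC and at 0 in the other wild type groups. Xist, the RNA that silences an X chromosome in females, was at 0.181 CPM in WT BM MNC, 1450 CPM in WT HSPC and 2100 CPM in WT MP. The libraries labelled WT BM MNC thus carried male transcripts and the other wild type groups female ones, so comparisons with WT BM MNC may also hold a difference of sex. Progenitor genes were thus higher in the libraries labelled mononuclear cells than in those labelled HSPC. WT BM MNC means the libraries with that label.

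Against the libraries labelled WT BM MNC, the 7 leukemia models together gained T lineage genes and lost B, granulocyte and stem cell genes. Cd3e, a subunit of the T cell receptor complex (ENSMUSG00000032093, GRCm38 chromosome 9, 44998740 to 45009627), averaged 275 ± 77.8 CPM over the models (SD of group means, n = 7; 21 libraries) and was at 0 in WT BM MNC, at least 2400-fold higher. Cd8b1, the CD8 beta chain (ENSMUSG00000053044, chromosome 6, 71322788 to 71337494), averaged 221 ± 129 CPM and was at least 1930-fold higher. Ptcra, the pre-T cell receptor alpha chain of thymocytes (ENSMUSG00000036858, chromosome 17, 46755663 to 46763712), averaged 138 ± 108 CPM and was at least 1200-fold higher. Syt13, a synaptotagmin family member (ENSMUSG00000027220, chromosome 2, 92915098 to 92956058), averaged 321 ± 102 CPM, at least 2800-fold above WT BM MNC. Arsi, a sulfatase, Slc16a5, a transporter, Pgpep1l and the adenylate cyclase Adcy1 were also at 0 in WT BM MNC and at least 2560-, 611-, 454- and 448-fold higher. Cd3g had 2 counts in WT BM MNC, a ratio of 3800 (95% interval 1080 to 32200), and Cd163l1, a scavenger receptor of gamma-delta T cells, had 1 count, a ratio of 8310 (1290 to 283000). Of the genes that fell, Pax5, the B lineage commitment factor (ENSMUSG00000014030, chromosome 4, 44524757 to 44710487), was at 0.869 CPM against 82.2 ± 7.11 CPM, 94.6-fold lower. Igll1 and Vpreb3, genes of pre-B cells, were 86.4- and 428-fold lower, and Ebf1, a B lineage transcription factor, 117-fold lower. Cplx2, Myct1, Prss50, the chromatin protein Hmga2, Sh2d4a and the red cell and liver pyruvate kinase Pklr were 38.9-fold (Pklr) to 272-fold (Cplx2) lower.

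Lineage lists moved in unlike directions in this comparison, and some did not pass. T and NK cell genes rose, 12 of 20 rising and 6 falling (median log2 6.19, camera adjusted p = 2.43e-07), with Cd3e and Cd3g among the risers. Of mature neutrophil genes 22 of 23 fell (median log2 −4.24, adjusted p = 1.25e-20), and of primary granule genes 12 of 13 fell (−5.26, 2.66e-14), among them Elane and Mpo, a protease and a peroxidase of granules, at −6.76 and −6.73. Stem cell genes fell, 20 of 21 (adjusted p = 6.3e-08), with Gata2 at −7.27 and Cd34 at −7.20; the list median was −4.68, or −4.19 with genes of a group at 0 set to their bound. Erythroid genes fell, 15 of 19 (adjusted p = 4.87e-08), as did megakaryocyte genes, 12 of 13 (2.77e-04), mast cell, basophil and eosinophil genes, 11 of 12 (4.8e-06), and B cell genes, 14 of 18 (4.67e-05). The Hoxa-Meis1 programme, typical of myeloid leukemia with MLL fusions, fell in 10 of 12 members (adjusted p = 0.00319). Monocyte genes, 7 up and 9 down of 21, did not pass (adjusted p = 0.279), nor did dendritic cell and MHC class II genes (2 up, 9 down of 13, adjusted p = 0.0866), MHC class I genes (5 up, 7 down of 13, adjusted p = 0.349) or stromal genes (5 up, 9 down of 15, adjusted p = 0.932). Each of the list calls held with an estimated correlation, at adjusted p of 0.0197 or lower.

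**Figure D1:**
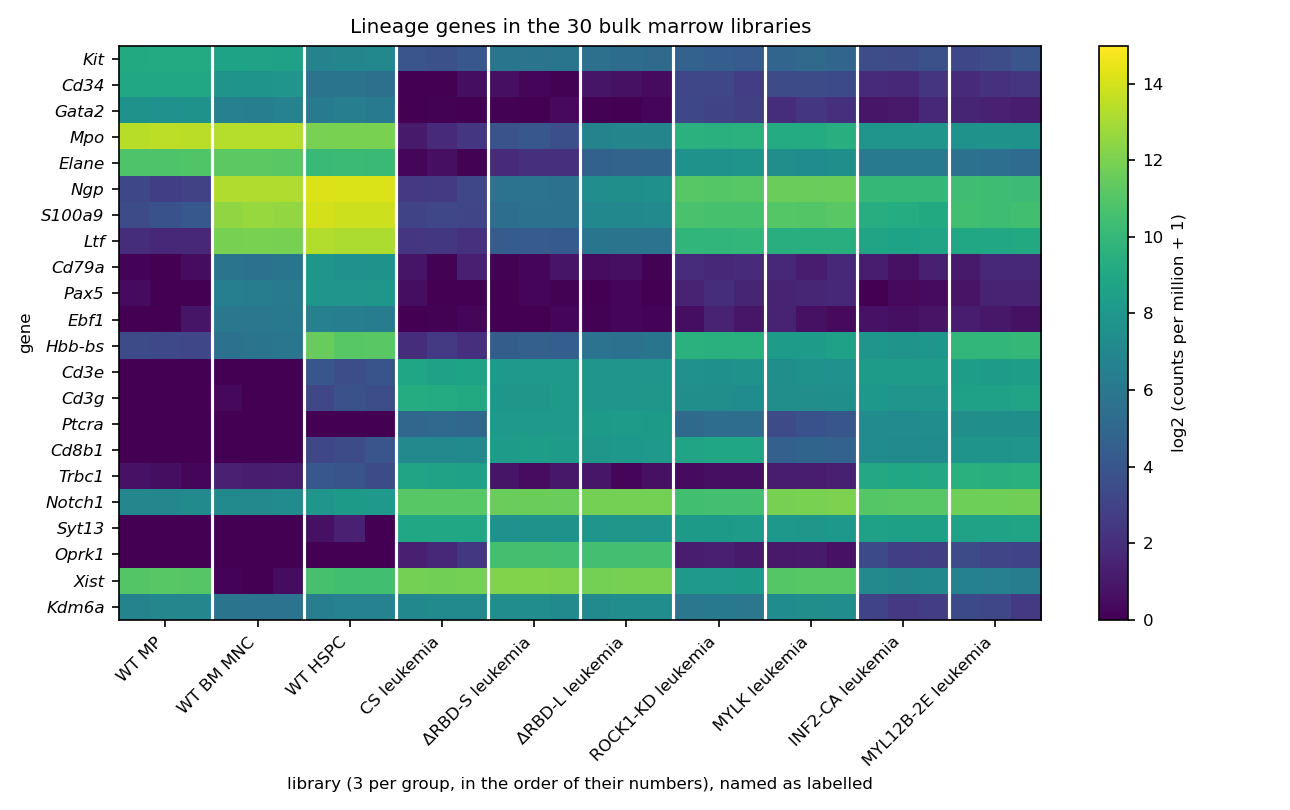
Heatmap of log2(CPM + 1) for 22 lineage genes (vertical axis) in the 30 bulk marrow libraries (horizontal axis, 3 per group). Cd3e is at 176 CPM or more in all 21 leukemia libraries and at 15.1 CPM or less in every wild type library.

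Innate sensing and cytoskeletal lists lay lower in the leukemia models than in WT BM MNC. Of 37 interferon-stimulated genes 25 fell and 5 rose, 6 when adjusted over the list alone (median log2 −1.02, camera adjusted p = 0.01). Ifi44 was at −6.63, Oas1a, a sensor of double-stranded RNA, at −4.14 and Ifi27l2a at −3.95, while Ifi204, a DNA-binding interferon-inducible protein, rose by 3.77. In the cGAS-STING and nucleic acid sensing list 17 of 22 fell and 5 rose (adjusted p = 0.0359), with Samhd1, a dNTP hydrolase, at −3.31, Tlr3 at −3.07 and the STING inhibitor Nlrc3 at 2.16. Tmem173 itself rose by 0.61 (SE 0.06) and averaged 96.2 CPM in the models and 47.9 CPM in WT BM MNC, but only ΔRBD-S, ΔRBD-L and ROCK1-KD lay above WT BM MNC, at 219, 168 and 128 CPM, and the other 4 models lay below it, at 30.7 to 46.1 CPM. Cgas, the DNA sensor before it, fell by 0.99 (SE 0.09) and ranged from 10.8 to 49.4 CPM between models, against 40.8 CPM. Of 45 actomyosin genes 31 fell, 32 when adjusted over the list alone, and 8 rose (median −0.57, or −0.48 with genes at their bound, adjusted p = 8.93e-04). Rhob, a small GTPase of actin dynamics, was at −3.65, the tropomyosin Tpm2 at −2.94, vinculin (Vcl) at −2.75 and Mylk at −2.48. Rock1 averaged 172 CPM against 128 CPM, Rhoa, which activates it, 350 against 419 CPM, and Inf2 18.5 against 60.8 CPM, all past the test. Myl12b was at 2.00 CPM or less in all marrow groups, an uncertain value given its overlapping annotation. SRF/MRTF targets, the genes that follow actin state, fell in 13 of 22 members (adjusted p = 4.83e-04), and NF-kB and cytokine genes in 14 of 24 (adjusted p = 0.0363). All of these calls held with an estimated correlation, at adjusted p between 0.00326 and 0.0392. T cell receptor genes rose and neutrophil genes fell in the same libraries by far more, as given for the lineage lists.

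Ribosome biogenesis and MYC genes fell, 22 of 25 (median log2 −0.35, camera adjusted p = 0.00108), as did cell cycle genes, 31 of 40 (−0.26, adjusted p = 0.0049), stress response genes, 14 of 20 (adjusted p = 0.00953), and immediate early genes, 13 of 16 (adjusted p = 7.85e-08), all also with an estimated correlation (0.0272 or lower). Nuclear-encoded oxidative phosphorylation genes (7 up, 27 down of 47, adjusted p = 0.153) and mitochondrial dynamics genes (5 up, 17 down of 29, adjusted p = 0.089) did not pass. Nor did vesicle release genes (4 up, 9 down of 18, adjusted p = 0.115), glycolysis genes (7 up, 11 down of 20, adjusted p = 0.153) and ribosomal protein genes (16 up, 11 down of 36, adjusted p = 0.199). YAP/TAZ targets (3 up, 10 down of 17, adjusted p = 0.192), interferon-gamma-inducible genes (3 up, 9 down of 14, adjusted p = 0.675) and integrins (8 up, 12 down of 21, adjusted p = 0.826) did not pass either. For p53 targets (6 up, 9 down of 18) the median was −0.28 while the test pointed up, at adjusted p = 0.742. In all, the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 4835 genes up and 6459 down, 11294 of 15995. Without the INF2-CA leukemia libraries, left out after the data were seen, it called 11293.

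The wild type group set the direction of some lists. Against the libraries labelled WT HSPC, a reference chosen after the data were seen, interferon-stimulated genes (2 up, 32 down of 37, camera adjusted p = 1.27e-05), actomyosin genes (5 up, 37 down of 45, adjusted p = 3.82e-08) and nucleic acid sensing genes (3 up, 15 down of 22, adjusted p = 0.0209) again fell. MYC genes rose there, 24 of 25 (adjusted p = 9.65e-10), and ribosomal protein genes rose, 36 of 36 (adjusted p = 2.06e-10; adjusted p = 0.0525 with an estimated correlation). T and NK cell genes rose against WT HSPC too (11 up, 9 down, adjusted p = 0.00258). The fall of cell cycle genes did not pass against WT HSPC (14 up, 20 down of 40, adjusted p = 0.951) or against the mean of the 3 wild type groups (adjusted p = 0.95). Against that mean monocyte genes fell (adjusted p = 0.00298), while the falls of MYC (0.811) and B cell genes (0.676) did not pass. The calls for nucleic acid sensing and for T and NK cell genes ended there only with an estimated correlation (adjusted p = 0.0746 and 0.0935). The edgeR fit called 11553 genes against WT HSPC and 12076 against the mean of the 3 wild type groups.

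The libraries of sorted WT MP cells gave a purer progenitor reference. Dtx1, an E3 ligase that Notch induces, averaged 722 CPM in the models and was at 0 in WT MP, at least 4350-fold higher, and Il2ra, the interleukin-2 receptor alpha chain of early thymocytes, averaged 785 CPM (40.8 to 2350 between models), at least 4720-fold higher. Tcrg-C4, Tcrg-C2, Cd3d, Cd2 and Zap70, of T cell receptors and their signaling, were at least 2360-, 2020-, 1520-, 1390- and 1170-fold higher, and Syt13, Cd3g and Cd3e at least 1930-, 1770- and 1650-fold. Cd34 fell from 499 ± 15.5 to 3.44 CPM, 145-fold, Gata2, a stem cell transcription factor, from 200 ± 10.2 to 2.01 CPM, 99.5-fold, and Meis1, a Hox cofactor, from 86.8 ± 6.41 to 0.46 CPM, 189-fold. Nkx2-3, a homeobox gene, was at 21 ± 3.71 CPM in WT MP and 0 in the models, at least 1940-fold lower. Myct1, Prss50, Epha7, the chemokine Ccl4 and Ptgs2, the inducible cyclooxygenase, were 275-, 142-, 304-, 136- and 121-fold lower.

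Cell cycle genes rose against WT MP, 25 of 40, with 12 falling (median log2 0.38, camera adjusted p = 0.00198), and mature neutrophil genes rose, 15 of 23, or 16 adjusted over the list alone (adjusted p = 0.00154). MYC genes fell, 25 of 25 (adjusted p = 2.9e-08), as did stem cell genes, 20 of 21 (adjusted p = 3.39e-10), primary granule genes, 12 of 13 (adjusted p = 1.94e-12), immediate early genes, 15 of 16 (adjusted p = 9.24e-13), NF-kB genes, 18 of 24 (adjusted p = 3.85e-06), and erythroid genes, 13 of 19 (adjusted p = 4.88e-04). T and NK cell genes rose, 13 of 20 (adjusted p = 1.33e-06). Ribosomal protein genes fell, 28 of 36 (adjusted p = 0.0026), as did MHC class I genes, 7 of 13 (adjusted p = 0.0283), but with an estimated correlation these were at adjusted p = 0.363 and adjusted p = 0.175; the other calls held, the weakest at 0.0477. Interferon-stimulated (9 up, 20 down, adjusted p = 0.241), nucleic acid sensing (5 up, 14 down, adjusted p = 0.165) and actomyosin genes (15 up, 25 down, adjusted p = 0.323) did not pass. The edgeR quasi-likelihood test called 5038 genes up and 6011 down, 11049 in all (5508 up and 5444 down in a fit on the compared groups only), and 11002 without the INF2-CA leukemia libraries.

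CS leukemia lost granulocyte and red cell genes against WT BM MNC. Elane, neutrophil elastase (ENSMUSG00000020125, chromosome 10, 79886247 to 79888215), was at 0.251 CPM against 2360 ± 35.4 CPM (SD, n = 3), 9400-fold lower. Add2, an erythroid membrane skeleton adducin, was at 0 against 189 ± 9.87 CPM, at least 2670-fold lower, and Rhag, of the Rh complex of red cells, Gca and Parp8 at least 1540-, 1980- and 1650-fold lower. Syt13 reached 497 ± 7.34 CPM and Cd3e 414 ± 31.5 CPM, at least 4340- and 3620-fold higher, and Arsi, Cd8b1 and Iqch at least 2280-, 1180- and 882-fold higher. Mature neutrophil genes fell in 23 of 23 members (camera adjusted p = 2.74e-25) and erythroid genes in 19 of 19 (adjusted p = 3.08e-16). Interferon-stimulated genes fell, 25 of 37 (adjusted p = 0.00439), as did nucleic acid sensing genes, 15 of 22 (adjusted p = 0.0203), and actomyosin genes, 30 of 45 (adjusted p = 5.63e-04), all with an estimated correlation too (0.0358 or lower). Ribosomal protein genes rose, 30 of 36 (adjusted p = 5.89e-05; adjusted p = 0.216 with an estimated correlation). By the edgeR quasi-likelihood test 5238 genes rose and 5877 fell, 11115 in all.

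ΔRBD-S and ΔRBD-L leukemia shared the gain of Oprk1, the kappa opioid receptor (ENSMUSG00000025905, chromosome 1, 5588466 to 5606131). Their single cells lay in the same main clusters, and a common origin of both leukemias was not tested. It stood at 1500 ± 30.3 CPM in ΔRBD-S and 1480 ± 33.5 CPM in ΔRBD-L (SD, n = 3) and at 0 in WT BM MNC, at least 13100- and 13000-fold higher. In ΔRBD-S, Arsi, Strc, the stereocilin gene, Cd8b1 and Cd3e were at least 7840-, 3270-, 2750- and 2340-fold higher. There Hlf, a stem cell transcription factor, Cplx2 and Slc25a21 were at 0, at least 632-, 726- and 553-fold lower, and Pklr and Sphk1, sphingosine kinase, were 4510-fold (1240 to 36900) and 4290-fold (805 to 177000) lower. In ΔRBD-L, Arsi, Ptcra, Cd8b1 and Syt13 were at least 4180-, 2550-, 2240- and 2070-fold higher, Myct1, Sh2d4a and Aldh1a7 at least 467-, 335- and 265-fold lower, and Pax5 1200-fold (429 to 6090) and Pklr 1840-fold lower. Cell cycle genes fell in both, 38 of 40 in ΔRBD-S (camera adjusted p = 2.2e-10) and 33 of 40 in ΔRBD-L (adjusted p = 8.99e-06), and actomyosin genes fell, 33 and 32 of 45 (adjusted p = 3.48e-04 and 6.36e-05), each also with an estimated correlation. Interferon-stimulated genes did not pass (12 up, 18 down in ΔRBD-S, adjusted p = 0.273; 7 up, 22 down in ΔRBD-L, adjusted p = 0.116). In ΔRBD-S interferon-gamma-inducible genes rose, 7 of 14, with 3 falling (adjusted p = 0.0431; adjusted p = 0.057 with an estimated correlation). Called genes in the edgeR quasi-likelihood test numbered 11550 in ΔRBD-S (5275 up, 6275 down) and 11610 in ΔRBD-L (5265 up, 6345 down).

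Rock1, the gene named in the ROCK1-KD label (ENSMUSG00000024290, chromosome 18, 10064401 to 10182045), was at 142, 145.5 and 146.4 CPM in the leukemia libraries labelled ROCK1-KD and at 127.6, 119.4 and 136.4 CPM in those labelled WT BM MNC. It was thus not lower in the libraries labelled ROCK1-KD, although their mean, 145 ± 2.35 CPM, was the lowest of the 7 models. Cd163l1 reached 1110 ± 15 CPM there, a ratio of 31100 (5190 to 1140000), and Cd8b1 443 ± 8.15 CPM, at least 3870-fold higher. Syt13, Cd3e and Eppk1, epiplakin, were at least 2520-, 1670- and 1130-fold higher. The pre-B genes Igll1, Vpreb3 and Vpreb1 were 504-, 156- and 84-fold lower, with Cplx2 89.1-fold and Gfra2, a growth factor coreceptor, 504-fold (132 to 3960) lower. Genes of mitochondrial dynamics and quality control fell, 23 of 29 (camera adjusted p = 5.21e-04), also with an estimated correlation (0.00344). Interferon-stimulated (8 up, 23 down, adjusted p = 0.0745) and actomyosin genes (16 up, 21 down of 45, adjusted p = 0.438) did not pass. Mature neutrophil genes fell, 16 of 23, with 5 rising (adjusted p = 3.1e-07). Ribosomal protein genes rose, 26 of 36 (adjusted p = 8.4e-04; adjusted p = 0.298 with an estimated correlation). In the edgeR quasi-likelihood test 4862 genes rose and 5187 fell, 10049 in all.

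MYLK leukemia carried Ccn4, a secreted matricellular target of Wnt signaling, at 335 ± 10 CPM (SD, n = 3) against 0 in WT BM MNC, at least 2920-fold higher. Syt13, Cd3e, Mpzl2 and Adcy1 were at least 2190-, 1650-, 861- and 294-fold higher. Vpreb3 was 898-fold (227 to 6780), Hmga2 483-fold (83.9 to 18600), Vpreb1 297-fold, Cplx2 255-fold and Mogat2 189-fold lower. MYC genes fell in 25 of 25 members (camera adjusted p = 3.58e-11) and cell cycle genes in 33 of 40 (adjusted p = 1.28e-07), while p53 targets rose, 9 of 18 (adjusted p = 0.0126), all also with an estimated correlation, the weakest at 0.0466. Actomyosin genes fell, 28 of 45 (adjusted p = 0.00978; adjusted p = 0.11 with an estimated correlation). Interferon-stimulated genes (5 up, 21 down, adjusted p = 0.0651) did not pass. By the edgeR quasi-likelihood test 5061 genes rose and 6046 fell, 11107 in all.

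INF2-CA and MYL12B-2E leukemia shared H2-T3, the nonclassical MHC gene of thymus leukemia antigen. It was at 264 CPM in the bulk libraries labelled INF2-CA and 437 CPM in MYL12B-2E, at least 2300- and 3810-fold above WT BM MNC. Syt13 was at least 3230- and 3560-fold higher, Cd3e at least 2680- and 2840-fold and Iqch at least 1650- and 1770-fold, with Arsi at least 2270-fold higher in INF2-CA and Cd8b1 at least 1930-fold higher in MYL12B-2E. Igll1 was at 0 in INF2-CA, at least 931-fold lower, and 3120-fold (509 to 112000) lower in MYL12B-2E, where Vpreb1 was 1430-fold (232 to 51300), Vpreb3 659-fold (197 to 2800) and Mmrn1, a platelet multimerin, 197-fold (69.3 to 993) lower and Prss50 at least 216-fold lower. In INF2-CA, Fosb, an immediate early AP-1 member, was 1180-fold (400 to 5680), Vpreb3 833-fold (235 to 7030), Pax5 383-fold and Cplx2 224-fold lower. Interferon-stimulated genes fell in INF2-CA, 24 of 37 (camera adjusted p = 0.00358), and MYL12B-2E, 23 of 37 (adjusted p = 0.00823), as did nucleic acid sensing genes, 15 and 17 of 22 (adjusted p = 0.00733 and 0.00178), all also with an estimated correlation. Cell cycle genes rose in MYL12B-2E, 34 of 40 (adjusted p = 8.24e-06), while in INF2-CA 10 rose and 19 fell (adjusted p = 0.242). Actomyosin genes fell, 27 and 26 of 45 (adjusted p = 0.00896 and 0.0483), but with an estimated correlation these were at adjusted p = 0.105 and adjusted p = 0.213. Called genes in the edgeR quasi-likelihood test numbered 10843 in INF2-CA (4983 up, 5860 down) and 11110 in MYL12B-2E (5116 up, 5994 down). Whether a list's change differed between models was not tested. In each of the 7 models the called genes that fell outnumbered those that rose, but this turned under at least 1 other setting in every model: without the low count filter 5868 rose and 5741 fell in CS, and in a fit on the compared groups only 5165 rose and 5071 fell in MYLK.

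**Figure D2:**
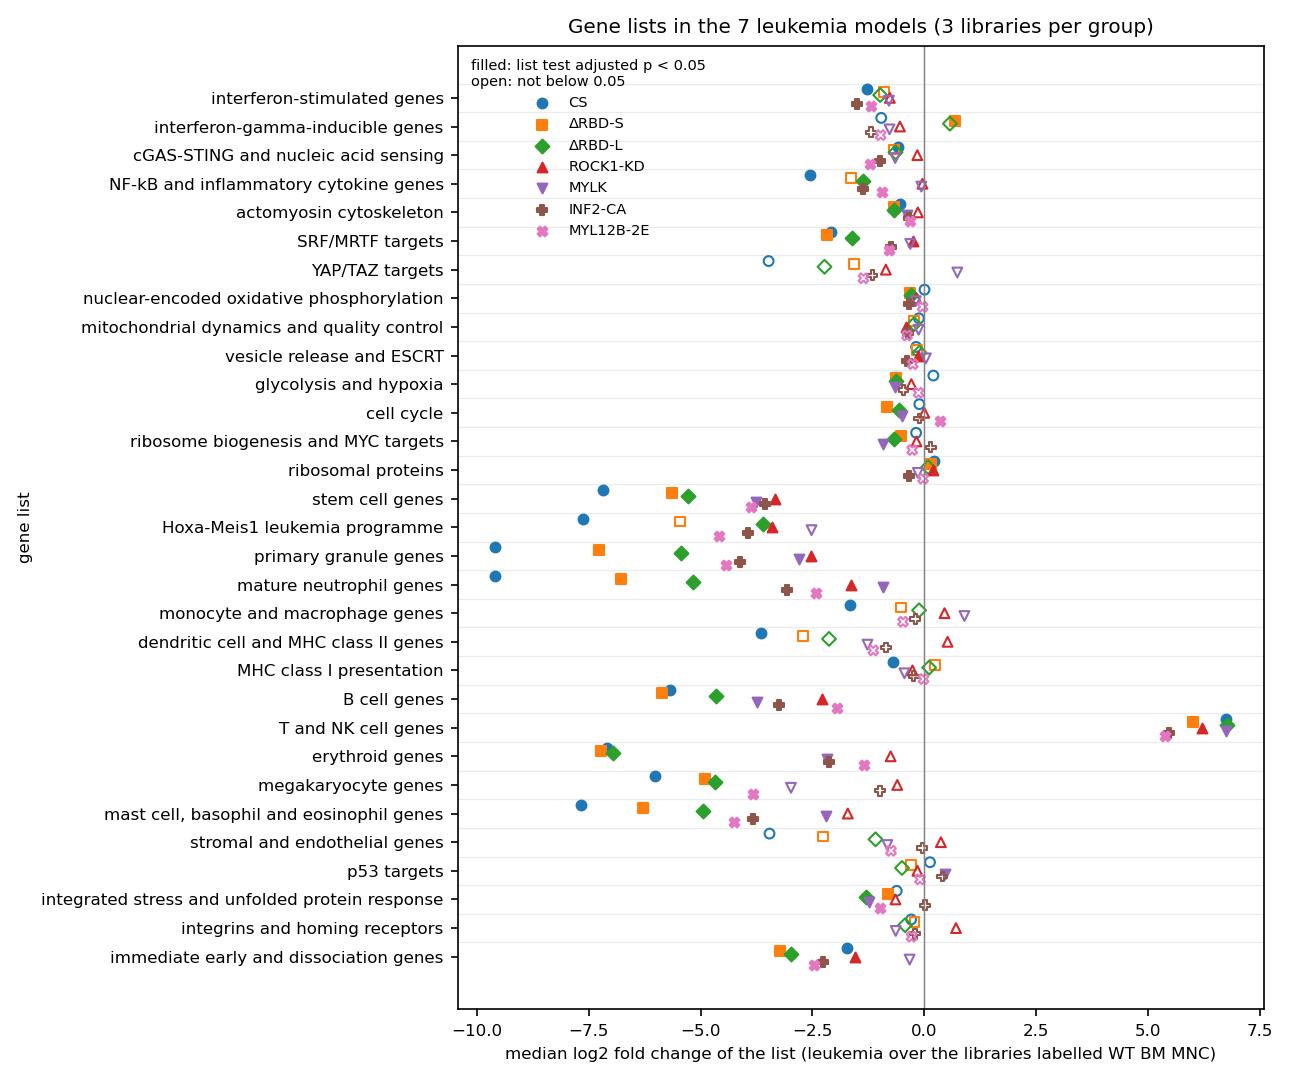
Median log2 fold change of each gene list (vertical axis) in the 7 leukemia models (horizontal axis) against the libraries labelled WT BM MNC; filled points mark lists with a camera adjusted p under 0.05. T and NK cell genes lie above 0 in all 7 models, and primary granule genes lie under 0 in all 7.

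Ngp, Oprk1 and Trbc1 were among the genes that differed between the models. The labels do not say that a model's libraries came from separate leukemias, so these are differences between the sequenced samples. Ngp, a neutrophil granule protein (ENSMUSG00000032484, chromosome 9, 110419747 to 110423012), ranged from 5.91 CPM in CS to 3149 CPM in MYLK, with 50.9 and 175 CPM in ΔRBD-S and ΔRBD-L and 1021 to 2192 CPM in the others. S100a9, an alarmin of neutrophils and monocytes, ranged from 7.94 CPM in CS to 2142 CPM in MYLK. Oprk1, at 1500 and 1480 CPM in ΔRBD-S and ΔRBD-L, was at most 8.25 CPM elsewhere. Trbc1, a T cell receptor beta constant gene (chromosome 6, 41538218 to 41539881), was at 402, 522 and 724 CPM in CS, INF2-CA and MYL12B-2E and at most 1.37 CPM in the other 4 models. Vwce was at 1804 CPM in MYLK and at most 101 CPM elsewhere. Chil3, Ltf, Lcn2 and Camp, of neutrophil granules, and the leukocyte protein Lsp1 complete the 10 genes with the smallest p among models, from 7.98e-101 for Ngp to 9.31e-91 for Lsp1 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p). Tmem173 differed too, as given above. The F test among models called 15040 genes, and 14838 without the INF2-CA libraries. By pair, 4826 genes differed between ΔRBD-S and ΔRBD-L, 6902 between INF2-CA and MYL12B-2E, and 9227 to 11399 in each of the other 19 pairs.

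ΔRBD-L leukemia had more granulocyte transcripts than ΔRBD-S leukemia. Prtn3, proteinase 3 (ENSMUSG00000057729, chromosome 10, 79874476 to 79883174), was at 43 ± 3.12 CPM (SD, n = 3) against 4.61 CPM, 9.32-fold higher (log2 3.21, SE 0.09, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 7.82e-48). Elane, Ctsg, cathepsin G, and Mpo were 8.62-, 8.14- and 8.06-fold higher and the matrix gene Fn1 6.84-fold higher. Neb, nebulin (chromosome 2, 52136647 to 52378474), was at 3.14 against 35.7 CPM, 11.4-fold lower, and the aryl hydrocarbon receptor Ahr, mast cell carboxypeptidase Cpa3, Khdc1a and the cytokine Lif were 3.98- to 4.46-fold lower. Mature neutrophil genes rose, 21 of 23 (camera adjusted p = 4.93e-30), as did cell cycle genes, 30 of 40, or 34 adjusted over the list alone (adjusted p = 4.34e-15), primary granule genes, 7 of 13 (adjusted p = 4.63e-10), and erythroid genes, 10 of 19 (adjusted p = 7.35e-05). MYC genes fell, 20 of 25 (adjusted p = 4.63e-10), glycolysis genes, 13 of 20 (adjusted p = 2.26e-06), interferon-gamma-inducible genes, 10 of 14 (adjusted p = 3.86e-04), and MHC class I genes, 8 of 13 (adjusted p = 5.77e-04), and all of these held with an estimated correlation (0.0143 or lower). Actomyosin genes fell, 18 of 45, with 5 rising (adjusted p = 0.0202; adjusted p = 0.159 with an estimated correlation); their median was −0.09 and their mean 0.07. Interferon-stimulated genes (5 up, 12 down, adjusted p = 0.177) did not pass. In all 2366 genes rose and 2460 fell, while with RLE scaling 2536 rose and 2289 fell.

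In the single-cell libraries, cells named T cell-like by their markers made up 5.37% of wild type marrow (Clopper-Pearson 95% interval 4.87 to 5.91). In wild type these 402 cells also carried NK cell genes, with Cd3e at 319 CPM and Ncr1, an NK cell receptor, at 174 CPM. They made up 96.8% of CS, 99.5% of ΔRBD-S, 98.6% of ΔRBD-L, 92.7% of MYLK, 92.6% of INF2-CA and 91.0% of MYL12B-2E cells. In ROCK1-KD they made up 23.5% (22.6 to 24.4). Cluster 11, found only there (3210 cells, 40.0%), had 7 T cell markers raised. It stayed unnamed for NK cell markers among its leading genes, which also held Tcrg-C4, Bcl11b, Tcf7 and Lef1. So 23.5% may be too low. At resolution 0.5 ROCK1-KD had 11.3% T cell-like cells and 16.4% mature neutrophils, up from 0.573%. Wild type marrow held 37.2% mature neutrophils (36.1 to 38.3), 14.0% B lineage cells, 10.2% monocytes or macrophages, 4.89% neutrophil precursors and 2.46% erythroid cells. The wild type T cell-like cells all lay in cluster 26, and nearly all leukemia ones lay in clusters without wild type cells. A cluster mostly of 1 library may reflect that library, and these shares rest on the marker genes themselves.

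**Figure D3:**
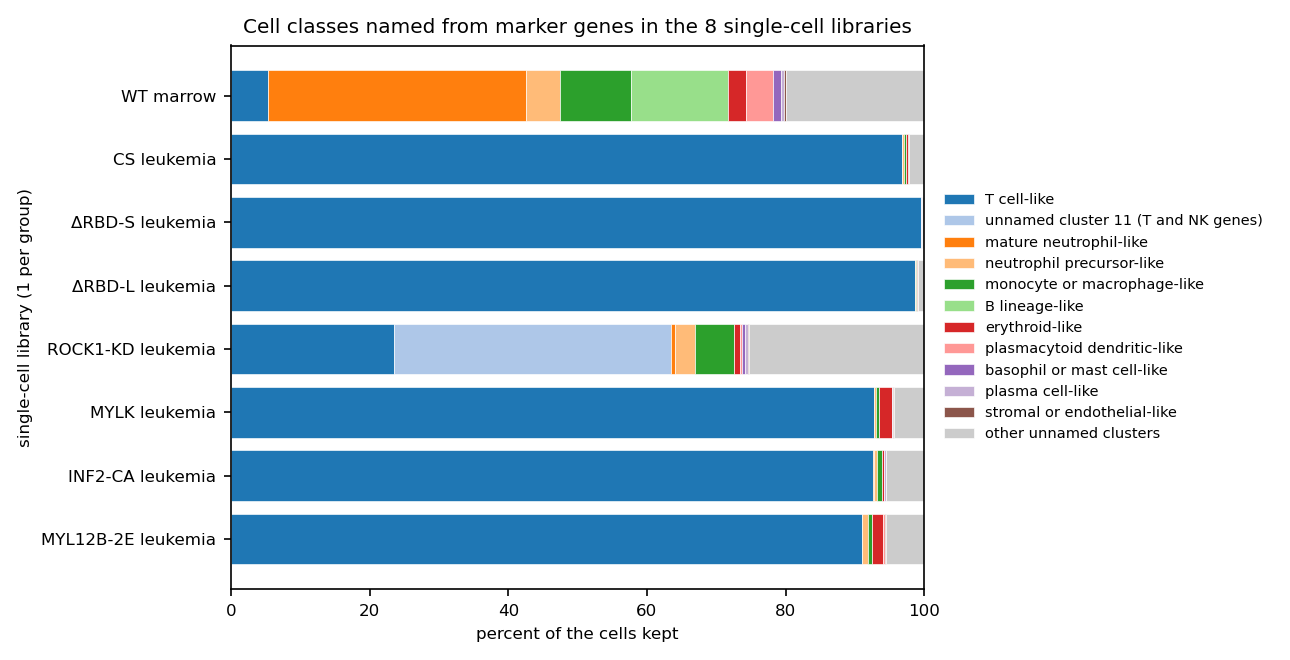
Percent of cells kept in each named class (stacked bars, vertical axis) in the 8 single-cell libraries, 1 per group. T cell-like cells fill 91.0 to 99.5% of 6 leukemia libraries and 5.37% of wild type. ROCK1-KD has 23.5% without cluster 11 (11.3% at resolution 0.5).

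Summed over all cells of a library, Syt13 was at 0.0399 CPM in wild type and 36.7 to 96.7 CPM in the leukemia libraries, a median ratio of 1080. Spats2 was at 0.339 CPM in wild type and 435-fold higher by the median ratio, and Fam183b, with 0 wild type UMIs, at least 555-fold. Tdrd5 had 1 wild type UMI, 0.00996 CPM (95% Poisson interval 0.000252 to 0.0555), and 2.79 to 57.5 CPM in leukemia. Inava had 3, 0.0299 CPM (0.00616 to 0.0874), and 0.943 to 51.4 CPM in leukemia. Prss34, a basophil protease, Siglech, a receptor of plasmacytoid dendritic cells, Ptgs2, Klk1 and Cd200r3 were lower in each leukemia library, by median factors of 8870, 944, 875, 785 and 668, with libraries at 0 set to 3 UMIs. Tmem173 was at 21.2 CPM in wild type, 62.9 (61.5 to 64.3) in ΔRBD-S, 61.8 in ΔRBD-L and 9.04 to 34.7 CPM in the other leukemia libraries. Rock1 was at 306 CPM in wild type, 228 CPM in ROCK1-KD, 225 CPM in CS and 220 CPM in MYLK. Within T cell-like cells, wild type cells carried NK receptor genes such as Ncr1 and Klre1, lower in leukemia by median factors of 11600 and 10900, with Xcl1, Klra4 and Klra7 lower by 12500, 8920 and 7760. The antigen Ly6d was 209-fold higher by the median ratio, with 19 wild type UMIs. Notch3, a Notch receptor of thymocytes, had 2 wild type UMIs, 0.576 CPM (95% Poisson interval 0.0698 to 2.08), and 50.2 to 172 CPM in leukemia, and Endou 1, 0.288 CPM (0.00729 to 1.6), and 185 to 549 CPM in leukemia. Ratios of this class set leukemia cells against a wild type mix of T and NK cells.

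By class, interferon-stimulated genes had a median log2 ratio to wild type of −2.17 to −1.61 over all cells and of −2.03 to −1.17 in T cell-like cells, depending on the leukemia library. In monocyte-like cells, of which ROCK1-KD had 443, MYLK 45, INF2-CA 68 and MYL12B-2E 58 against 766 in wild type, the same median was −1.33, −2.58, −1.72 and −2.47. Rsad2, the antiviral viperin, and the DNA-binding Ifi213 and Ifi206 were lower there by median factors of 14.7, 15.1 and 14.1. Phgdh, of serine synthesis, and the metallothionein Mt1 were 7.89- and 6.17-fold higher by the median ratio in these cells. Trbc2, a T cell receptor gene, was 34.7-fold higher in the same monocyte-like cells, and free RNA from T cell-like cells and doublets were not told apart there. Cell cycle genes were higher in the T cell-like cells of every leukemia library, 40 of 40, at median log2 ratios of 1.95 to 3.24. Oxidative phosphorylation genes lay 0.60 to 1.29 higher and MYC genes 0.80 to 1.41 higher by median log2 ratio in T cell-like cells.

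Bulk and single-cell libraries of a label were compared across 2728 genes, each as its difference from the mean of the models, with single cells taken from clusters of under 1% wild type cells. Genes are not independent replicates, so no p is given. In 6 models a label's bulk libraries correlated with its own single-cell library at Pearson r of 0.664 (MYLK) to 0.925 (ROCK1-KD), although ΔRBD-S bulk matched the ΔRBD-L single-cell library as closely (0.907) as its own (0.904), and ΔRBD-L bulk that of ΔRBD-S (0.892) more closely than its own (0.877). The bulk libraries labelled INF2-CA had r = 0.0787 with the INF2-CA single-cell library and 0.78 with that of MYL12B-2E. Kdm6a, a histone demethylase chosen after its values were seen, was at 5.81 CPM in INF2-CA bulk and 7.46 CPM in MYL12B-2E bulk. In single cells it was at 101 CPM (99.7 to 103) in INF2-CA and 10.6 CPM (10.1 to 11.2) in MYL12B-2E over all cells, and 0.159 CPM (0.0955 to 0.248) in the MYL12B-2E cells of those clusters. Values for INF2-CA leukemia are therefore given for the libraries carrying that label.

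**Figure D4:**
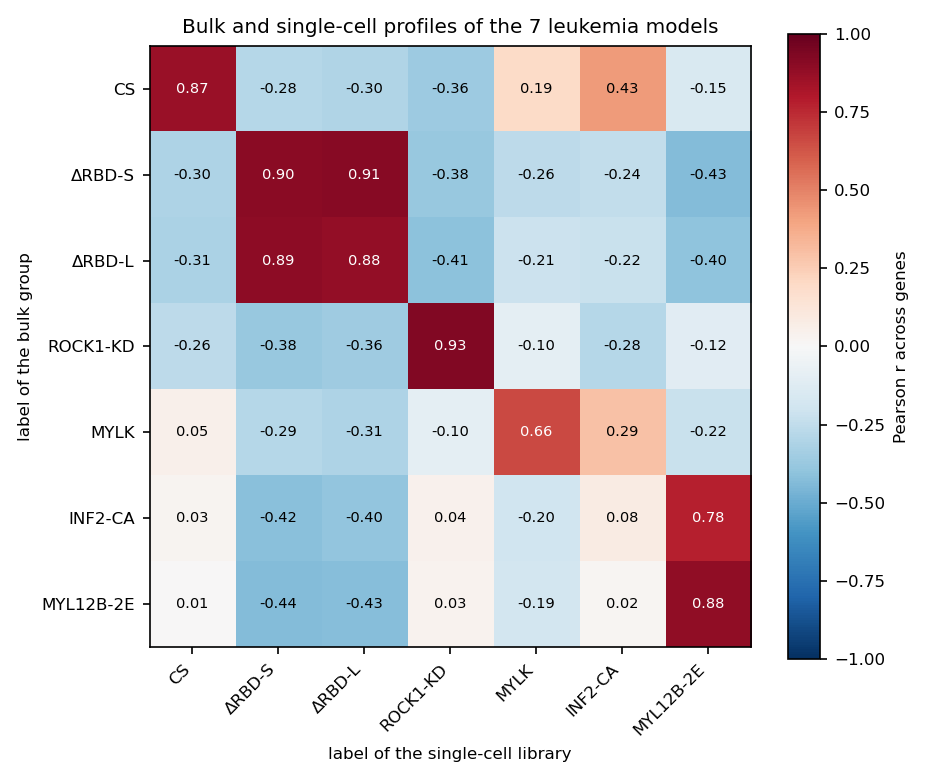
Pearson r across 2728 genes between the bulk libraries (rows) and the single-cell library (columns) of 7 leukemia models, each as its difference from the mean of the models. The diagonal holds 0.664 to 0.925 except for INF2-CA at 0.0787, whose row is highest, 0.78, under MYL12B-2E.

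In HSPC, the gene named by each construct was read first. Rock1 was at 121.9 and 118.6 CPM in the HSPC libraries labelled ROCK1-KD, 117 and 116.5 CPM in EV and 133.2 and 101.9 CPM in EV2, so it was not lower in the libraries labelled ROCK1-KD. Mylk was at 13.6 ± 1.6 CPM (SD, n = 2) in MYLK-HSPC, 6.53 CPM in EV and 8.84 CPM in EV2. Inf2 was at 119 CPM in INF2-CA-HSPC, 82 CPM in EV and 121 CPM in EV2. Directions for these constructs are those of the labelled libraries.

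Across the 5 constructs with a leukemia of their own, Gpnmb, a transmembrane glycoprotein of macrophages (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), averaged 280 ± 112 CPM (SD of group means, n = 5; 10 libraries). It was at 28.5 CPM in EV and 103 CPM in EV2, 9.8- and 2.72-fold lower than the constructs (log2 1.36, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.19e-18). Stard9, a kinesin, at 70.5 CPM, was 3.03- and 1.99-fold higher (adjusted p = 7.09e-05), and these 2 were the genes that met the naming rule in every construct. Genes of ribosome biogenesis and MYC fell, 18 of 25 and 21 adjusted over the list alone (camera adjusted p = 2.42e-17), with Polr1b, of RNA polymerase I, at −0.60 and Nolc1 at −0.53. Cell cycle genes fell, 9 of 40 and 13 over the list alone (adjusted p = 3.52e-05), as did mast cell genes, 5 of 15 (adjusted p = 2.85e-24; Hdc, histidine decarboxylase, −0.69, Cpa3 −0.51), and erythroid genes, 6 of 14 (adjusted p = 3.11e-04), all with an estimated correlation too, the weakest at 0.0476. Interferon-stimulated genes rose in 3 of 36 members, 4 adjusted over the list alone: Oas2 by 0.78 (SE 0.2), Stat2 by 0.48 (SE 0.08) and Trim30a by 0.42 (SE 0.12). That list's test gave adjusted p = 0.00503, and adjusted p = 0.17 with an estimated correlation. T and NK cell genes fell, 3 of 6 (adjusted p = 6.49e-06), and primary granule genes, 4 of 13 (adjusted p = 0.00565), but with an estimated correlation they were at adjusted p = 0.17 and adjusted p = 0.441. Of 44 actomyosin genes only Vim, vimentin, rose, by 0.32 (SE 0.04), and the list turned opposite ways against EV and EV2. Nucleic acid sensing genes rose in 3 of 22 members and did not pass as a list (adjusted p = 0.534). In the edgeR quasi-likelihood test 277 genes rose and 375 fell, 652 in all; against EV alone it called 5840 and against EV2 alone 2265, and without EV2 replicate 1, 379.

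**Figure D5:**
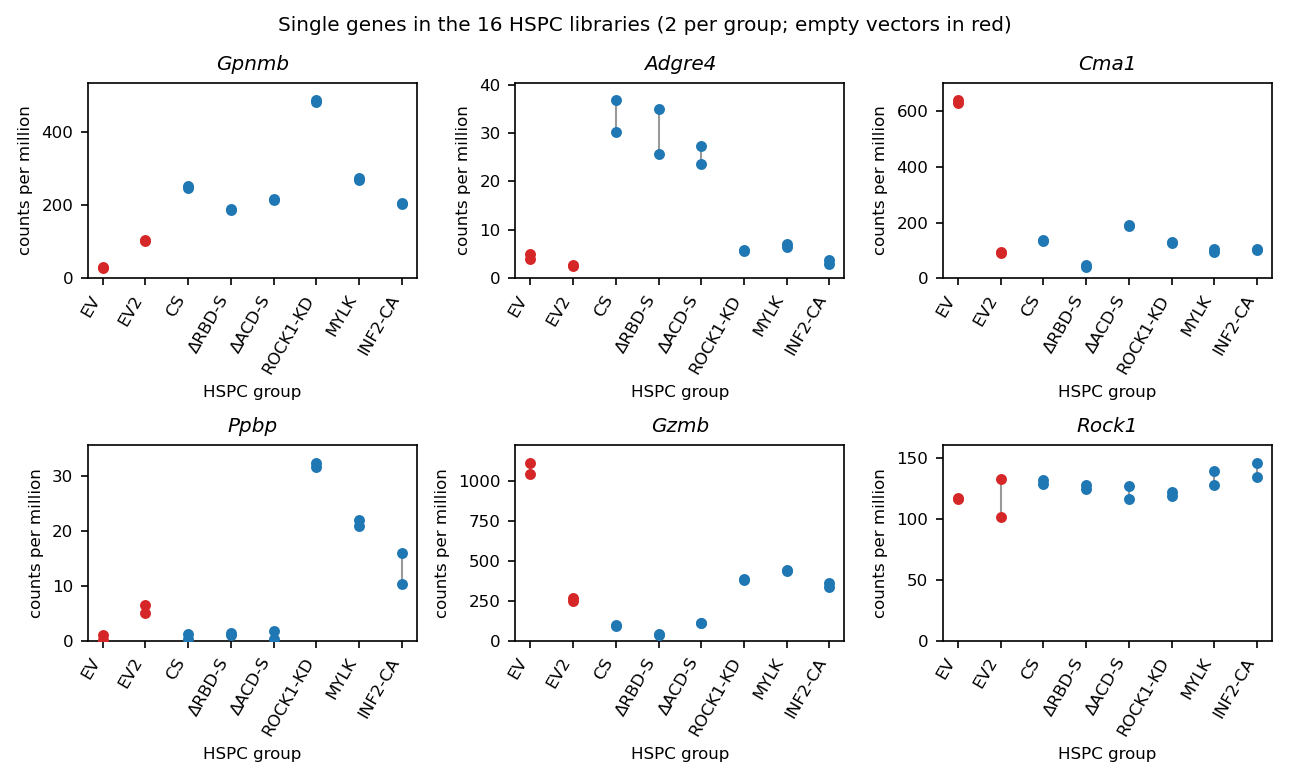
CPM (vertical axes) of Gpnmb, Adgre4, Cma1, Ppbp, Gzmb and Rock1 in the 16 HSPC libraries (points, 2 per group), with the empty vectors in red. Gpnmb averages 484 CPM in ROCK1-KD, 28.5 CPM in EV and 103 CPM in EV2, and Rock1 lies at 118.6 and 121.9 CPM in the libraries labelled ROCK1-KD.

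CS-HSPC gained Adgre4 and Saa3 and lost erythroid and mast cell genes. Adgre4, an adhesion receptor of macrophages (ENSMUSG00000032915, chromosome 17, 55749984 to 55853662), was at 33.5 ± 4.59 CPM (SD, n = 2), 7.56-fold above EV and 12.6-fold above EV2, and Saa3, serum amyloid A3, at 178 ± 5.49 CPM, 4.6- and 4.82-fold. Gbp8, an interferon-inducible GTPase, rose 12.0- and 4.33-fold, with ceruloplasmin (Cp), log2 2.11, and the stress gene Nupr1, 4.14- and 5.29-fold. Prkcq, protein kinase C theta, was 31.3- and 50.2-fold lower, Cd226 17.7- and 32.1-fold, Neb 10.5- and 12.1-fold, Mmp9 9.49- and 9.7-fold, and Gpr174 fell by 3.30 on the log2 scale. Erythroid genes fell, 9 of 14 and 13 over the list alone (camera adjusted p = 1.36e-06), mast cell genes, 10 of 15 (adjusted p = 1.77e-30; Prg2 −2.74, Hdc −1.80), and MYC genes, 14 of 25 (adjusted p = 5.67e-06), all with an estimated correlation too. Interferon-stimulated genes rose, 10 of 36 and 13 adjusted over the list alone (adjusted p = 0.00108; adjusted p = 0.116 with an estimated correlation), Oasl2 by 1.37 (SE 0.34) and Oas2 by 0.97. Targets of p53 rose, 8 of 18 (adjusted p = 0.00372; adjusted p = 0.0532 with an estimated correlation), Zmat3 by 1.20 and Trp53inp1 by 0.87. Cell cycle genes fell, 16 of 40 (adjusted p = 1.67e-04; adjusted p = 0.0595 with an estimated correlation). The edgeR quasi-likelihood test called 754 genes up and 1031 down, 1785 in all. Against EV alone, of the same technical set, it called 4792, against EV2 alone 4483, in a fit on the compared groups only 940, and without EV2 replicate 1, 1113.

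ΔRBD-S-HSPC and ΔACD-S-HSPC also gained Adgre4, 6.84- and 5.72-fold over EV and 11.4- and 9.55-fold over EV2. In ΔRBD-S, Myh11, a smooth muscle myosin, was at 11.1 ± 4.55 CPM (SD, n = 2) and at 0 in both vectors, at least 98.6- and 57.7-fold higher. The chemokine Cxcl10 was 5.57- and 5.38-fold higher, Stfa1 3.97- and 22-fold and the survival gene Bcl2a1a 4- and 3.21-fold. Cdh17, a cadherin, was 74- and 174-fold and Fgfr1 25.1- and 21.1-fold lower, with Prkcq, Cd226 and Hgfac falling by 4.60, 4.44 and 4.10 on the log2 scale. In ΔACD-S, Saa3 was 3.56- and 3.73-fold higher, Gbp8, the cysteine synthesis gene Cth and the lectin Clec4d had log2 values of 2.16, 1.68 and 1.66, Cd226 was 8.47- and 15.4-fold and Thy1 5.64- and 10-fold lower, and Mfsd2b, Prkcq and Crisp1 fell by 2.62, 2.61 and 2.52. Mast cell genes fell, 12 of 15 in ΔRBD-S (camera adjusted p = 2.47e-72; Prg2 −2.76, Hdc −2.52) and 8 of 15 in ΔACD-S (adjusted p = 2.47e-18), and MYC genes fell, 14 of 25 in each (adjusted p = 3.94e-05 and 3.88e-05), all with an estimated correlation too. Interferon-stimulated genes rose, 10 of 36 in each, 13 and 18 adjusted over the list alone (adjusted p = 7.94e-04 and 2.25e-04), with Oasl2 at 1.31 and Stat2 at 0.98 (SE 0.1) in ΔRBD-S and Oas2 at 1.34 and Xaf1 at 1.21 in ΔACD-S. With an estimated correlation these lists were at adjusted p = 0.154 and adjusted p = 0.0987. The edgeR quasi-likelihood test called 1704 genes in ΔRBD-S (676 up, 1028 down), 4798 against EV alone, 4382 against EV2 alone and 1090 without EV2 replicate 1. For ΔACD-S it called 1288 (514 up, 774 down), 4516 against EV alone, 3997 against EV2 alone and 701 in a fit on the compared groups only. The count for ΔACD-S was 828 without ΔACD-S replicate 2, 841 without ΔACD-S replicate 1 and 829 without EV2 replicate 1.

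ΔACD-S-HSPC and ΔRBD-S-HSPC, which share a technical set, differed in mast cell and cytokine genes. Cma1, mast cell chymase (ENSMUSG00000022225, chromosome 14, 55941451 to 55944675), was at 188 ± 2.58 CPM in ΔACD-S and 44.8 ± 5.76 CPM in ΔRBD-S (SD, n = 2), 4.2-fold higher (log2 2.06, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.16e-21). The mast cell proteases Mcpt2, Tpsg1 and Mcpt4 were 9.38-, 4.67- and 4.59-fold higher and Maob, a monoamine oxidase, 5.64-fold. Myh11 was 25-fold lower, Tnf at 18.5 against 60.1 CPM 3.24-fold lower, and Rasgef1b, Ccrl2 and Plk2 3.68-, 2.47- and 2.3-fold lower. Mast cell genes rose, 11 of 15 (camera adjusted p = 2.43e-141; Fcer1a 1.86, Tpsb2 1.83), and stem cell genes, 3 of 19 (adjusted p = 1.84e-04; Gata2 0.90, Cd34 0.79). NF-kB and cytokine genes fell, 9 of 25 and 11 over the list alone, with 1 rising (adjusted p = 1.09e-13; Ccl4 −1.13, Nfkbiz −1.05, Tnfaip3 −1.04). These 3 calls held with an estimated correlation (0.0312 or lower). In all 225 genes rose and 131 fell, 356 together. The count was 204 without ΔRBD-S replicate 1, 196 without ΔRBD-S replicate 2, 210 without ΔACD-S replicate 1 and 199 without ΔACD-S replicate 2.

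HSPC libraries labelled ROCK1-KD gained Ppbp and monocyte and immediate early genes. Ppbp, a platelet chemokine (ENSMUSG00000029372, chromosome 5, 90768518 to 90770063), was at 32.1 CPM, 49.1-fold above EV and 5.49-fold above EV2, and Gpnmb at 484 ± 3.56 CPM (SD, n = 2), 17- and 4.7-fold. Clmn, thrombomodulin (Thbd) and Slfn1 rose by log2 2.08, 2.07 and 2.00. Mid1, a microtubule-bound ubiquitin ligase, was 2.87- and 3.83-fold lower, Eif2b3, of translation initiation, 2.35- and 2.11-fold, and Cacnb2, Gnb1l and the Hedgehog receptor Smo fell by 1.37, 1.20 and 1.11 on the log2 scale. MYC genes fell, 24 of 25 (camera adjusted p = 2.55e-27; Nolc1 −1.10, Polr1b −1.05, Srm −1.01), as did cell cycle genes, 19 of 40 (adjusted p = 7.5e-11; Cdk1 −0.65), and primary granule genes, 9 of 13 (adjusted p = 8.44e-13; Ms4a3 −0.85, Mpo −0.84). Monocyte genes rose, 12 of 20 (adjusted p = 9.44e-17; Ctss 1.21, Mrc1 1.08), immediate early genes, 11 of 16 (adjusted p = 1.19e-14; Btg2 1.77, Fos 1.21), integrins, 9 of 21 (adjusted p = 0.00264), and interferon-gamma-inducible genes, 3 of 12 and 6 over the list alone (adjusted p = 0.00176; Cd274 0.92, Irf1 0.72). These calls held with an estimated correlation, the weakest at 0.0286. Megakaryocyte genes rose, 5 of 13 (adjusted p = 0.00208; Treml1 2.17, Vwf 1.27, Pf4 0.93), and MHC class II genes, 6 of 9 (adjusted p = 1.51e-04; Cd74 0.60), but with an estimated correlation they were at adjusted p = 0.116 and adjusted p = 0.0783. Interferon-stimulated genes rose in 5 of 36 members and did not pass as a list (adjusted p = 0.433), and actomyosin genes had 4 up and 5 down of 44. The edgeR quasi-likelihood test called 1132 genes up and 1004 down, 2136 in all (1030 up and 1060 down without the low count filter), with 3380 against EV2 alone, of the same technical set, 6243 against EV alone and 1432 without EV2 replicate 1.

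MYLK-HSPC and INF2-CA-HSPC changed fewer genes. In MYLK-HSPC, Ppbp was 32.9- and 3.68-fold above EV and EV2 and Gpnmb 9.52- and 2.64-fold, with the complement gene C1qc at log2 1.60 and Oas1g at 1.29. Trib3, a pseudokinase induced by ATF4, was at 8.4 CPM against 48.3 and 29.7 CPM, 5.75- and 3.53-fold lower, Camp, the cathelicidin, 2- and 2.07-fold lower, and Cth, Gpt2 and Stc2 fell by 1.22, 1.08 and 0.95 on the log2 scale. In INF2-CA-HSPC, the Ras pathway inhibitor Spry2 was 2.51- and 2.45-fold higher and Nos2, inducible nitric oxide synthase, 301-fold (86.9 to 2600) and 4.94-fold, with Plekha6 at log2 1.17 and Rfx3 at 1.06. Ltf, lactoferrin, was at 745 CPM, 1.46- and 1.79-fold lower, Camp 1.75- and 1.81-fold lower, and Retnlg, Clec4b2 and Rrs1 fell by 1.13, 0.81 and 0.51. Stress response genes fell in MYLK-HSPC, 3 of 20 and 7 over the list alone (camera adjusted p = 9.17e-04; Asns −0.75, Atf4 −0.27; adjusted p = 0.159 with an estimated correlation). Megakaryocyte genes rose there, 2 of 13 (adjusted p = 0.00171; Pf4 0.84; adjusted p = 0.159 with an estimated correlation). MYC genes fell in INF2-CA-HSPC, 2 of 25 and 11 over the list alone (adjusted p = 1.64e-08), with an estimated correlation too (0.0314). Glycolysis and hypoxia genes rose there, 5 of 20 and 8 over the list alone (adjusted p = 0.00779; Egln3 0.99, Slc2a1 0.48; adjusted p = 0.585 with an estimated correlation). The edgeR quasi-likelihood test called 133 genes in MYLK-HSPC (82 up, 51 down), 417 against EV2 alone and 4522 against EV alone, and 84 in INF2-CA-HSPC (60 up, 24 down), 209 against EV2 alone and 5134 against EV alone. A fit on the compared groups only called 59 and 39. The MYLK count was 64 without MYLK replicate 1 and 72 without MYLK replicate 2, and the INF2-CA count 33 without INF2-CA replicate 1, 37 without INF2-CA replicate 2 and 243 without EV2 replicate 1.

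The empty vectors differed from each other, with technical set and vector confounded. Arg1, arginase of alternatively activated macrophages (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), was at 313 ± 28.3 CPM in EV2 and 3.77 CPM in EV (SD, n = 2), 83-fold higher (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.64e-34). The chemokine Ccl24, the scavenger receptor Cd36 and the arginine transporter Slc7a2 were 47.7-, 41- and 30.5-fold higher, and Car4 at least 123-fold. Cma1 was at 92.5 against 635 CPM, 6.86-fold lower, Calca 20.4-fold, Stfa3 14-fold, Acsbg1 8.75-fold lower, and Kcne3 fell by 2.68 on the log2 scale. Monocyte genes rose, 19 of 20 (median log2 2.08, camera adjusted p = 1.22e-67), MHC class II genes, 8 of 9 (adjusted p = 1.09e-34), NF-kB genes, 17 of 25 (adjusted p = 7.6e-16; Il1a 4.86, Il1b 2.79), and immediate early genes, 11 of 16 (adjusted p = 1.45e-16), and each held with an estimated correlation. Ribosomal protein genes fell, 34 of 36 (adjusted p = 1.42e-16), and oxidative phosphorylation genes, 34 of 47 (adjusted p = 1.39e-08), at adjusted p = 0.109 and adjusted p = 0.0994 with an estimated correlation. In all 2247 genes rose and 2017 fell, 4264 together, and 2394 in a fit on the compared groups only.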

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

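Chosen only after the result was seen were the tests on the T lineage pattern, on the INF2-CA bulk libraries and on Kit in the wild type libraries, and the single genes given first; the rank comparison of the wild type labels and the splits of the samples were set before.

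Single genes stood out because their change from the libraries labelled WT BM MNC differed between models in the edgeR quasi-likelihood test of the difference, 3 libraries per group. The biological coefficient of variation, the relative spread beyond counting error, was only 0.042 (ΔRBD-S) to 0.0775 (CS) within leukemia groups. Libraries of a model may come from the same leukemia, so differences between constructs were not told apart from differences between single leukemias. Tmem173, the STING gene (ENSMUSG00000024349, GRCm38 chromosome 18, 35733679 to 35740554), differed by a log2 value of 2.84 (SE 0.07, Benjamini-Hochberg adjusted p = 4.8e-51) between ΔRBD-S and INF2-CA leukemia, at 219 ± 5.85 against 30.7 ± 1.95 CPM. Mx1, an interferon-induced GTPase (chromosome 16, 97447035 to 97462907), was at 41.5 ± 3.15 CPM in MYLK and 0.144 CPM in CS leukemia (adjusted p = 4.35e-32, edgeR). Xist, the RNA that silences an X chromosome (chromosome X, 103460366 to 103483254), differed by 5.34 (SE 0.05, edgeR adjusted p = 1.31e-82) between CS and MYL12B-2E leukemia, at 3630 against 88.6 CPM. In WT BM MNC it was at 0.181 CPM, so this reference differs from CS leukemia in a sex marker. Kdm6a (ENSMUSG00000037369, chromosome X, 18162575 to 18279936) differed by 4.1 (SE 0.1, edgeR adjusted p = 3.24e-52) between the same models, at 135 ± 8.77 against 7.46 ± 2.41 CPM. Ngp differed by 8.55 (SE 0.06, edgeR adjusted p = 1.32e-91) between ROCK1-KD and CS leukemia, at 2192 against 5.91 CPM. Among HTSeq's summary lines, which the comparisons do not use, reads without a feature reached 13.2% in the EV2 set of HSPC libraries and 1.43% in the EV set.

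All leukemia groups, labelled acute myeloid leukemia, were high in T lineage genes and low in myeloid genes. In bulk, 21 of 21 leukemia libraries had Cd3e above every wild type library, at 176 CPM or more against 15.1 CPM or less. That argues against a mislabelled WT HSPC library among those labelled leukemia. For WT BM MNC and WT MP the rule that named Cd3e had already required this, so it is no test there. Leukemia labels exchanged with each other cannot be seen this way. Admixed normal T cells with many receptors, as the source of the T lineage transcripts, are argued against in 5 of 7 groups, in bulk and single cells alike. In ΔRBD-S, ΔRBD-L, ROCK1-KD and MYLK, Trbc1 made up at most 0.152% of both beta constant genes in bulk and 0.596% in T cell-like cells, against 36.5% in wild type T cell-like cells, and in CS 1 beta segment held 97.4% and 97.7%. Normal T cells stay open in INF2-CA bulk, with Trbc1 at 33.1%, and in MYL12B-2E, with 34.8% and 38.3%: at most 0.283% of the T cell-like cells of either library lay in cluster 26, which held the wild type T cell-like cells, but that cluster mixes T and NK cells and cannot stand for normal T cells or thymocytes. In INF2-CA single cells Trbc1 was at 0.0155%, unlike the bulk libraries of that label. Trbc1 beside Trbc2 does not by itself show many receptors: CS bulk had Trbc1 at 36.5% with 1 beta segment at 97.4%. Expansion of T lineage clones stays open: 1 beta segment held at least 50% of the beta segment UMIs in 3 of 7 single-cell leukemia libraries (Trbv2 97.7% in CS, Trbv12-2 98.5% in MYLK, Trbv2 95.5% in INF2-CA) and less in the other 4. In bulk it did so in 4 of 7 groups (Trbv2 97.4% in CS, Trbv13-3 61.7% in ΔRBD-S and 68.9% in ΔRBD-L, Trbv12-2 99.6% in MYLK), with Trbv13-2 at 22.8% in INF2-CA. The leading segment was the same in both assays only in CS and MYLK, at 97.4% or more. Bulk was led by Trbv14 in ROCK1-KD (45.1%) and Trbv13-2 in MYL12B-2E (22.2%). Single cells were led by Trbv12-2 in ΔRBD-S (47.5%), ΔRBD-L (43.4%) and ROCK1-KD (44.9%) and by Trbv5 in MYL12B-2E (29.3%). Beta segments in these 4 libraries totalled 5.28 to 38.7 CPM beside 431 to 2350 CPM of Trbc2, so their shares cannot decide. Leukemias of T lineage stay a hypothesis drawn from these data, and whether the constructs set the lineage was not tested.

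Between the bulk and the single-cell data the INF2-CA label did not match itself, with r = 0.0787 across genes. A general assay difference is argued against by the other 6 labels, which matched themselves at 0.664 or above. ΔRBD-S and ΔRBD-L bulk, though, matched each other's single-cell library at least as well as their own. An exchange of the INF2-CA and MYL12B-2E bulk libraries is argued against, since MYL12B-2E bulk had r = 0.0234 with INF2-CA single cells and 0.884 with its own. The INF2-CA bulk libraries may hold cells of the MYL12B-2E leukemia or of 1 with the same origin, since their r with the MYL12B-2E single-cell library was 0.78. A shared biology of both constructs in other animals than the one used for single cells stays open and was not tested. For ΔRBD-S and ΔRBD-L a common origin stays open too. Their cells shared their main clusters, with 3826 and 3682 cells in cluster 0, and their profiles had r = 0.973 in single cells and 0.926 in bulk.

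The libraries labelled WT BM MNC were high in progenitor genes and those labelled WT HSPC in genes of mature cells. An exchange of these labels would make the WT HSPC libraries the closer match to wild type marrow single cells. They were: Spearman's rho across genes, which are not independent replicates, was 0.873 to 0.877 for WT HSPC and 0.851 to 0.852 for WT BM MNC, a gap of 0.021 between the nearest libraries, so the values are consistent with exchanged labels. Against a pure Kit-positive sort in the WT BM MNC libraries stand Ngp, Ltf and Camp, at 9510, 3940 and 2630 CPM there and 7.01, 2.39 and 2.05 CPM in WT MP. Mature cells mixed into a correct HSPC sort stay open, since Kit, 3.46 times as high in WT BM MNC as in WT HSPC, is part of the pattern itself. Mononuclear cells enriched for progenitors before sequencing stay open, and no biological explanation was tested.

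Chance assignment of single libraries could be excluded for the pooled results. These splits part the libraries of a group, which lie close together, and whole groups can be reassigned in only 8 ways in a comparison of 7 groups with 1, too few for a share under 0.05. For the 7 leukemia models against WT BM MNC, 1 of 100 splits of the same libraries, the real one, called 11294 genes, and the highest other called 3918. Against WT MP the real split called 11049 and the highest other 2492, and among the 7 models the values were 15040 and 8771, again 1 of 100 splits each. The comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05. Their real and highest other values were 11115 and 1 for CS, 4826 and 1 for ΔRBD-L against ΔRBD-S, and 11550, 11610, 10049, 11107, 10843 and 11110 with a highest other of 0 for ΔRBD-S, ΔRBD-L, ROCK1-KD, MYLK, INF2-CA and MYL12B-2E.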

How the results depend on the processing

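Chosen only after the result was seen were the other wild type references and the pools without the INF2-CA leukemia libraries. No named gene changed direction under the alternatives run for it. MYC genes, which fell against WT BM MNC, rose against WT HSPC in 24 of 25 members. Whether more called genes rose or fell changed sides in 58 of 280 counts under alternatives, over 11 of 19 comparisons: all 7 single models, the models against WT MP, ΔRBD-L against ΔRBD-S leukemia (2644 up and 2355 down with DESeq2), ROCK1-KD-HSPC and MYLK-HSPC; the cause was not tested. Of 20 counts of called genes, all stayed within 1.5 times the reported count under RLE scaling (0.952 to 1 times), without the low count filter (0.914 to 1.36), with DESeq2 (0.915 to 1.04) and with a term for replicate number (0.985 to 1.1). Libraries deviated most like those of their own replicate number in 11 of 30 marrow libraries, 2 of 8 HSPC libraries of the EV2 set and 8 of 8 of the EV set, where the mean correlation was 0.0301, a hint from the data and not from the design. The other wild type references (1 to 1.07 times) and the pools without INF2-CA leukemia (0.987 to 1) stayed within it too. Of 2514 values of 130 named genes under alternatives, 2451 stayed past the threshold and 63 did not, 56 of them with a library left out.

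The empty vector decided the HSPC counts. Against EV alone and EV2 alone the counts were 5840 and 2265 for the pool, 4792 and 4483 for CS, 4798 and 4382 for ΔRBD-S, 4516 and 3997 for ΔACD-S, 6243 and 3380 for ROCK1-KD, 4522 and 417 for MYLK, and 5134 and 209 for INF2-CA. They exceed the reported counts by construction, since a gene then has to pass 1 test. A fit on the compared groups only, with fewer libraries to estimate the spread, gave 940 for CS, 701 for ΔACD-S, 59 for MYLK, 39 for INF2-CA and 2394 for EV2 against EV. The interferon-stimulated list in the HSPC pool was at adjusted p = 0.17 with an estimated correlation; the cause was not tested.

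With each library left out, counts ranged from 379 to 701 for the HSPC pool, 1113 to 1958 for CS, 1090 to 1830 for ΔRBD-S, 828 to 1433 for ΔACD-S, 64 to 182 for MYLK, 33 to 243 for INF2-CA and 196 to 210 for ΔACD-S against ΔRBD-S. For ROCK1-KD they ranged from 1432 to 2159 and for EV2 against EV from 2852 to 4292. An arm left with 1 library is assumed to vary like the other groups. The pooled leukemia counts ranged from 10751 to 11511 against WT BM MNC and from 10162 to 11173 against WT MP.

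The share of lymphoid cells under the looser cell filter was 15.6% in wild type, 96.1% in CS, 99.2% in ΔRBD-S, 98.2% in ΔRBD-L, 17.9% in ROCK1-KD, 90.9% in MYLK and 90.3% in MYL12B-2E. In ROCK1-KD it was 11.7% at resolution 0.5 and 25.4% with doublets kept, against 23.8% as reported. With cells thinned to 3000 UMIs, the median log2 ratio of the named lower genes was −10.97 in T cell-like and −2.92 in erythroid cells. That of the named higher genes was 4.24 in erythroid cells and 4.53 in neutrophil precursors. The cause was not tested. EV2 replicate 2, at 1187468 counts, limits what can be seen against EV2.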

Other observations

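The tests on the Kdm6a region were written before their result was seen, while the genes in this part were chosen after their values were seen.

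Notch1, Cd8a, Cd4, Ace and Il2ra had unlike levels in the models in bulk marrow. Notch1, the receptor that drives T lineage commitment, was at 1451 to 4080 CPM in the 7 leukemia models and at 127.5 to 258.8 CPM in the wild type groups (means, n = 3 each). In single cells Notch1 was at 66.4 CPM in wild type and 161 to 684 CPM in the leukemia libraries. Cd8a was at 483 and 807 CPM in INF2-CA and MYL12B-2E, 251 to 396 CPM in CS, ΔRBD-S and ΔRBD-L, and 19.9 and 17.9 CPM in ROCK1-KD and MYLK. Cd4 was highest in MYLK, at 236 CPM, and lowest in INF2-CA and MYL12B-2E, at 12.6 and 11.7 CPM. Ace, angiotensin-converting enzyme, was at 652 and 778 CPM in INF2-CA and MYL12B-2E and at most 77.5 CPM in the other 5 models. Il2ra was at 2350 CPM in ΔRBD-S, 1490 CPM in ΔRBD-L and 40.8 CPM in ROCK1-KD.

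In HSPC, Bnip3, a mitophagy receptor induced by hypoxia, had a log2 value of 1.00 (SE 0.1) in INF2-CA-HSPC. B2m, the light chain of MHC class I, rose by 0.64 (SE 0.06) in CS-HSPC. Tmem173 was at 114 ± 5.83 CPM (SD, n = 2) in the HSPC libraries labelled ROCK1-KD, 53.8 CPM in EV and 88.2 ± 34.9 CPM in EV2.

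Kdm6a was at 5.81 and 7.46 CPM in the bulk libraries labelled INF2-CA and MYL12B-2E, against 152 CPM over CS, ΔRBD-S, ΔRBD-L and MYLK, log2 differences of −4.71 and −4.27. As a hypothesis of this re-analysis, a lost segment of chromosome X around the gene might lower its neighbours by as much. Within 1e+06 bases only Fundc1, a mitophagy receptor (17556564 to 17572325), could be tested, and its log2 difference was −0.461 in INF2-CA and −0.464 in MYL12B-2E, at 27.5 CPM in each against 37.9 CPM. That argues against a loss that reaches Fundc1, and a smaller one stays open. In ROCK1-KD, Kdm6a was at 64.3 CPM, a log2 difference of −1.24, and Fundc1 at −0.533.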
